A study of Mus musculus with 69 samples.

How the data were processed

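Expression in dorsal skin was measured on 69 Affymetrix arrays. Biotin-labelled RNA was prepared from total RNA, per the labels' protocols. The deposited values are log2 expression values for 35556 probe sets, between 0.206 and 14.839, and RMA is the tool that the submitters' processing notes name, without a version. RMA corrects background, normalises arrays to a common distribution and summarises probes on the log2 scale. How batches were treated before deposit is not given in the sources used here. The labels give 3 batches, and the deposited values look aligned between them: over all 69 arrays the mean of a gene differed between batches 1 and 2 with an SD of only 0.0402 over genes, and the spread of variable genes in batch 2 was 0.962 of that in batch 1. Without the 2 arrays of narrow range that ratio was 0.745. All 27 FVB arrays are batch 1, and F1 and SPR arrays lie in batches 2 and 3. Such an alignment removes level differences between FVB and the other strains and may compress changes in batch 2, so only changes within a strain were compared with FVB.

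Groups were taken from the labels' strain and hours. The labels leave the strain of 3 arrays open, and the time of 1 of them, and these entered no comparison. The treatment protocol describes a single dose or vehicle and sampling to 1 week, while the samples also include 12 h and 1008 h, and the series' design text speaks of replicate exposure. No vehicle arrays are among the samples, so controls were the 9 arrays of 0 h, whose skin the labels give as untreated, and effects of vehicle, of shaving and of age at 1008 h are not separated from those of TPA. Time of day was not given.

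Probe sets were named through the platform annotation: 21218 had 1 gene symbol, 1881 had several and were not used, and 12457 were not in that table and stay unnamed here. Gene IDs were found in a reference table for 21185 of them, and 0 symbols needed updating. Each of 18820 genes was represented by its probe set with the highest mean over the 66 assigned arrays. No coordinates are given because no build is named for the array annotation. No column of another series was present and no pair of arrays held identical values.

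Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, in 1 model of 27 group means with a term for batch 3 against batch 2, leaving 38 residual degrees of freedom. All groups share 1 estimate of spread per gene, so a group of 1 array left by an alternative is assumed to vary like the others. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with an absolute log2 change of at least 1. Errors after ± are standard errors of the fit. Moderated F tests over times, and over differences of changes between strains, used the same adjusted p without a fold threshold. With 3 arrays against 3, a permutation test could not go below p = 0.1, so no such test was run on single genes.

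In all, 28 gene lists were written before the data were examined and tested with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists and times within a strain. Of 224 tests in FVB, 92 were called at the preset and 11 of them also with an estimated correlation. For F1 it was 100 and 17 of 196, and for SPR 61 and 5 of 140. A member of a list is said to rise or fall only if it was called as a gene. The list score of an array is the mean over members of log2 values centred on each gene's mean.

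A rule written before the data were examined gave the genes that could be named. Which of them to describe was chosen afterwards, and not all are named. In FVB they are the 5 largest rises and 5 largest falls per time among called genes with 1 ordinary symbol whose 3 treated arrays all lay beyond the control arrays on 1 side, a condition met by chance in 10.0% of genes. To these come up to 4 members of each list with the largest change. In F1 and SPR they are the 3 largest rises and falls, with the list members, and between strains the 10 largest F statistics. Lists of transcripts abundant in liver and in pancreas, and of hair matrix regulators, were drawn up once the values were known.

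Alternatives written before the data were examined were eBayes with trend and robust settings, centring on array medians, cyclic loess, leaving out dim probe sets, all probe sets, no fold threshold, each strain fitted alone, a replicate block, no batch term, batches 2 and 3 alone, genes with similar untreated level in SPR, and each array left out. Centring on medians moved the median log2 change by up to 0.14 in FVB at 24 and 1008 h and by -0.18 in SPR at 12 h, while changes in the report are those of the deposited scale. Chosen after seeing the data were leaving out the 2 narrow arrays, 2 FVB controls with liver transcripts, and 3 FVB arrays that stood apart in lists of cell types (replicate 3 at 6 h, replicate 1 at 48 h and replicate 3 at 72 h).

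The steps were tested on simulated arrays with the real gene means and spreads, with 200 of 18820 genes changed at FVB 24 h. Of those changed by 1.5 on the log2 scale 90.0% were recovered and of those changed by 3 it was 99.0%, with 9 false calls, and none in the unchanged 48 h group. The simulated noise was independent between genes and arrays, without batch differences or narrow arrays. These rates thus check the steps and need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.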

Results

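The series measured gene expression in mouse dorsal skin on Affymetrix arrays after topical TPA, a phorbol ester that activates protein kinase C and brings on inflammation and epidermal thickening. FVB is an inbred laboratory strain, SPR stands for the wild-derived Spret/Ei, and F1 for the cross of the FVB and Spret/Ei strains. Of 69 arrays, 66 had a strain and a time, with 27 from FVB, 25 from F1 and 14 from SPR in 27 groups. Each FVB group held 3 arrays, at 0, 2, 6, 12, 24, 48, 72, 168 and 1008 h. F1 had 4 arrays at 0 h, 6 at 1008 h, 3 at 48 h, and 2 at 4, 6, 12, 24 and 72 h. SPR had 2 arrays at 0, 4, 12, 24, 48 and 1008 h. A single array stood for F1 at 2 and 168 h and for SPR at 2 and 6 h, and these were not tested. All comparisons were made against untreated skin of the same strain at 0 h. The number of arrays limits the precision of every value. Nothing in the labels ties an array to a mouse of its own, so the p-values measure the spread between arrays, which may be technical in part.

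The arrays had log2 interquartile ranges between 3.32 and 3.72, except for replicate 1 of SPR at 12 h, with 1.63, and replicate 2 of F1 at 72 h, with 2.47. The median correlation of these 2 arrays with the others across genes was 0.780 and 0.933, against at least 0.941 for every other assigned array. They were kept in the fit, and the counts without them, an alternative chosen after seeing the data, are given beside those they move. Both are of batch 2 and also stayed in the fit of that batch alone, where they enter the estimate of spread. The fit of batch 3 alone held neither. In FVB, the number of called genes was highest at 6 h, with 2319, fell to 72 at 168 h, and stood at 1532 at 1008 h. The moderated F test over all times called 9588 genes in FVB and 5024 in F1, where it called 908 within batch 2. In SPR it called 6647 genes, 2544 without the 2 narrow arrays, 2973 after cyclic loess, 2393 within batch 2 and 17 with SPR fitted alone.

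**Figure D1:**
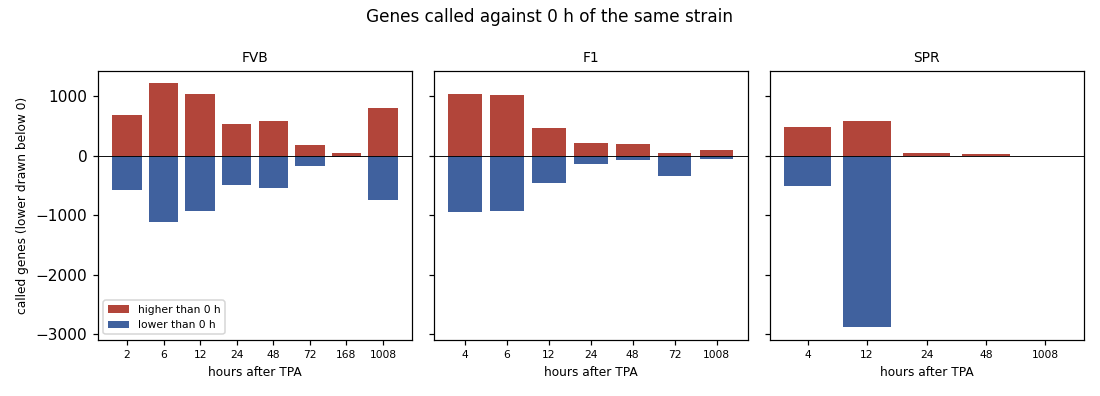
Number of genes called against 0 h of the same strain (vertical axis, genes higher drawn above 0 and genes lower drawn below 0) at each time in hours (horizontal axis), in 1 panel per strain. The 3468 genes of SPR at 12 h and the 374 of F1 at 72 h come from groups that hold an array with a narrow range of values.

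At 2 h, cytokines and chemokines had the largest mean change of the fixed lists in FVB skin, 2.71. The largest rises were those of Tnfaip6 (probe set 10472050), a hyaluronan-binding protein induced by inflammation, by 5.97 ± 0.60 on the log2 scale (SE, n = 3 and 3). Next came the neutrophil chemokine Cxcl2 by 5.78 ± 0.57, Il6 by 5.68 ± 0.38, the monocyte chemokine Ccl2 by 5.05 ± 0.45 and the cholesterol hydroxylase Ch25h by 4.75 ± 0.45. Il6 rose 51.4-fold (adjusted p = 4.42e-15). The largest falls were those of the claudin Cldn8 by 2.79 ± 0.29, of Mir181b-1 by 2.76 ± 0.48, of Sostdc1, a secreted antagonist of BMP and Wnt signals, by 2.55 ± 0.30, of Cyp4a31 by 2.51 ± 0.58 and of the prothrombin gene F2 by 2.37 ± 0.71.

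Among immediate early genes, 14 of the 15 measured members rose (14 adjusted over the list alone), led by Atf3 (2.76), Egr2 (2.47), Ier3 (2.31) and Zfp36 (2.21) (adjusted p = 1.90e-24 by camera, adjusted p = 0.00691 with an estimated correlation). Of the cytokines and chemokines, 17 of the 22 measured members rose (18 adjusted over the list alone), with Ccl20 at 4.45 ± 0.59 (adjusted p = 6.71e-28 by camera, adjusted p = 0.00112 with an estimated correlation). Ligands of the EGF receptor and their feedback genes rose at the same time, 10 of the 15 measured members (10 adjusted over the list alone). Among them were the ligands Hbegf (4.03), Epgn (3.45) and Ereg (3.03) and the phosphatase gene Dusp6 at 3.50 ± 0.31 (adjusted p = 4.51e-14 by camera, adjusted p = 0.00761 with an estimated correlation). Of stress keratins and small proline-rich proteins, made by activated keratinocytes, 15 of the 23 measured members rose (15 adjusted over the list alone), as did 9 of 17 proteases and remodelling genes, with Adamts4 at 4.66 ± 0.29. Camera with an estimated correlation gave adjusted p = 0.224 for the former and adjusted p = 0.174 for the latter. Of the mitosis genes, 7 of the 25 measured members fell (7 adjusted over the list alone), led by Ccna2 (1.23) and Bub1b (1.21) (adjusted p = 0.345 with an estimated correlation), and without the 2 FVB controls rich in liver transcripts these 2 genes stood at -1.14 and -1.10 (adjusted p = 0.0936 and 0.0898). The leukocyte adhesion genes Icam1 (3.12), Selp (2.93) and Sele (2.24) rose, as did the Langerhans cell marker Cd207 at 2.44 ± 0.41 and the neutrophil chemokine receptor Cxcr2 at 3.14 ± 0.56.

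In all, 1258 genes were called at 2 h, 678 higher and 580 lower (limma, n = 3 and 3), and 803 were called without replicate 2 of the 2 h group. Of a list of 25 transcripts abundant in liver, drawn up once the values were known, all were at least 1 log2 unit higher in replicates 2 and 3 of the FVB controls than in replicate 1, by medians of 2.80 and 3.37, and 12 of them, F2 included, fell at 2 h. In replicate 1, 2 of the 25 stood above the median gene. Of 14 pancreas transcripts, 8 were higher in both arrays in the same way. Without those 2 controls, an alternative chosen after seeing the data that leaves 1 control and so a larger error, 758 genes were called at 2 h. F2, Cyp4a31 and Mir181b-1 then stood at -0.50, -0.19 and -2.05 (adjusted p = 0.891, 0.951 and 0.0691). Genes lower then outnumbered genes higher at 2 h (388 and 370), 6 h (1151 and 811), 12 h (938 and 664) and 24 h (366 and 249). It was the same at 48 h (161 and 64), 72 h (6 and 5) and 1008 h (619 and 442). Leaving out control 1 alone had this effect at 2 h (750 and 668), 48 h (600 and 486) and 72 h (373 and 132). Leaving out control 3 alone had it at 6 h (1213 and 1159), 12 h (1057 and 988), 24 h (625 and 481), 48 h (465 and 451) and 1008 h (807 and 746). So did leaving out replicate 1 at 6 h (1115 and 1103) and replicate 1 or 2 at 12 h (1196 and 1096, 995 and 909). After cyclic loess genes lower were also the more numerous at 6, 12 and 48 h (1154 and 1116, 1017 and 983, 636 and 620). With no fold threshold it was so at 2 h (1479 and 1227), 6 h (2372 and 2281) and 24 h (1385 and 1150). The same held at 72 h (346 and 276) and 1008 h (1836 and 1538), but not at 12, 48 and 168 h. At 72 h the counts were 208 and 182 with dim probe sets out and 210 and 201 with all probe sets. Without a batch term they were 199 and 181. Under trend and robust settings, median centring, cyclic loess, strain fitted alone and replicate block, genes higher led at 72 h. The call of F2 was also lost without replicate 2 or 3 of the controls or replicate 2 at 2 h (adjusted p = 0.0967, 0.161 and 0.0777), and that of Cyp4a31 without replicate 3 of the controls (adjusted p = 0.0574).

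**Figure D2:**
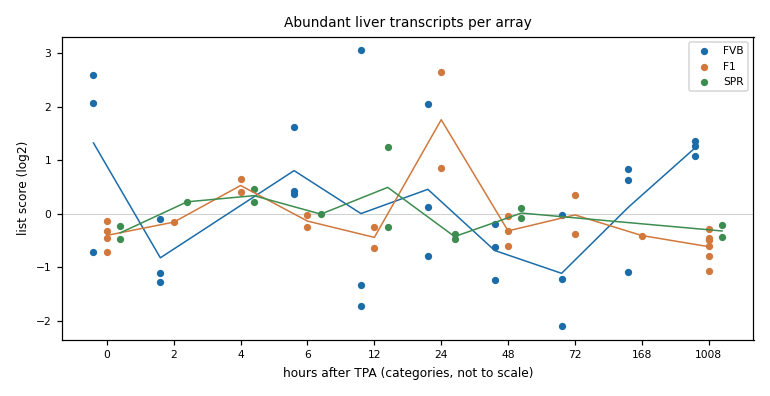
Score of 25 transcripts abundant in liver (vertical axis, mean of log2 values centred on each gene's mean over the assigned arrays) by time in hours, drawn as categories (horizontal axis). Points are arrays and lines join the means of each strain. FVB controls 2 and 3 reach 2.07 and 2.60 against -0.71 in control 1, and the score is also high in replicate 1 at 12 h (3.05) and 24 h (2.04) in FVB and in replicate 1 at 24 h in F1 (2.65).

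At 6 h the count of called genes in FVB was the highest of the course, at 2319, with 1213 higher and 1106 lower. The largest rises were Cxcr2 at 5.41 ± 0.56, the collagenase Mmp13 at 5.06 ± 0.62, the iron-sequestering protein Lcn2 at 4.95 ± 0.67, the chemokine Ccl3 at 4.92 ± 0.58 and Adamts4 at 4.87 ± 0.29. Adamts4 rose 29.2-fold (adjusted p = 1.16e-16). The largest falls were Slc16a14 by 4.01 ± 0.37, Fam171b by 3.55 ± 0.34, Vsnl1 by 3.54 ± 0.28, Sostdc1 by 3.50 ± 0.30 and the carbonic anhydrase Car6 by 3.40 ± 0.66. These 10 genes were called in every leave-one-out. Replicate 2 at 6 h had a liver score of 1.62.

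Of the cytokines and chemokines, 20 of the 22 measured members rose (20 adjusted over the list alone), with the epithelial cytokine Tslp at 4.82 ± 0.47 (adjusted p = 9.51e-24 by camera, adjusted p = 0.0022 with an estimated correlation). Of the proteases, 14 of the 17 measured members rose (14 adjusted over the list alone), with the protease inhibitor Timp1 at 4.82 ± 0.49 and the stromelysin Mmp3 at 3.92 ± 0.61 (adjusted p = 3.92e-16 by camera, adjusted p = 0.0241 with an estimated correlation). Of stress keratins and small proline-rich proteins, 19 of the 23 measured members rose (19 adjusted over the list alone), with Defb3 (4.61), Sprr2d (4.55) and Slpi (4.46) (adjusted p = 1.14e-17 by camera, adjusted p = 0.0878 with an estimated correlation). Of the neutrophil markers, 9 of the 15 measured members rose (9 adjusted over the list alone), with S100a9 at 3.91 ± 0.74 (adjusted p = 5.55e-06 by camera, adjusted p = 0.2 with an estimated correlation). Replicate 3 at 6 h stood apart, with a neutrophil score of 1.43 against 0.41 and 0.63, a lymphocyte score of 1.99 against -0.12 and -0.50, a macrophage score of 0.67 against -0.06 and -0.17, and a pancreas score of 3.54. Without it the neutrophil list kept its call (mean 1.44), as did S100a9 (3.56). Some probe sets of the Sprr2, Stfa and Krtap families may read near-identical paralogs, so single members of these families are uncertain. Of the mitosis genes, 8 of 25 fell, such as Ccna2 (1.92) and Mki67 (1.47) (adjusted p = 0.485 with an estimated correlation). Of the hair follicle stem cell markers, 4 of the 13 measured members fell (5 adjusted over the list alone), with Lgr5 down by 2.59 ± 0.34 and Lhx2 by 2.17 ± 0.35 (adjusted p = 6.12e-06 by camera, adjusted p = 0.247 with an estimated correlation).

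At 12 h, stress keratins and small proline-rich proteins had the largest mean change of the fixed lists, 3.26. In all, 1958 genes were called, 1028 higher and 930 lower (52.5% higher, and 63.3% with each array centred on its median). The beta-defensin Defb3 rose by 5.68 ± 0.75, the stefin Stfa3 by 5.37 ± 0.71, the chitinase-like Chil1 by 5.28 ± 0.72, Lcn2 by 5.17 ± 0.67 and Csta3 by 5.11 ± 0.73. Defb3 rose 51.1-fold (adjusted p = 4.20e-07). Car6 fell by 4.76 ± 0.66, the metallothionein Mt4 by 4.34 ± 0.38, the GABA receptor subunit Gabrp by 4.01 ± 0.59, Mrgprb3 by 3.97 ± 0.64 and Carns1, which makes carnosine, by 3.52 ± 0.43.

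Of stress keratins and small proline-rich proteins, 20 of the 23 measured members rose (20 adjusted over the list alone), with Krt16 (4.83) and Krt6b (4.83) (adjusted p = 2.51e-23 by camera, adjusted p = 0.0429 with an estimated correlation). Cytokines (18 of 22 rose, adjusted p = 0.00689 with an estimated correlation) and proteases (13 of 17 rose, adjusted p = 0.0429 with an estimated correlation) were still raised, and the neutrophil markers S100a8 and S100a9 stood at 4.74 ± 0.88 and 4.79 ± 0.74. Of the DNA replication genes, 7 of the 19 measured members rose (7 adjusted over the list alone), led by Rrm2 (1.66), Gins1 (1.47) and Ccne1 (1.37) (adjusted p = 9.47e-09 by camera, adjusted p = 0.345 with an estimated correlation). The suprabasal keratin Krt10 fell by 2.39 ± 0.44 and the cornified envelope gene Lor by 1.76 ± 0.36, while Lce3c rose by 4.34 ± 0.50. The collagen gene Col3a1 fell by 2.15 ± 0.52. Of the clock genes, 7 of the 15 measured members fell (7 adjusted over the list alone) and 2 rose, with Hlf down by 2.49 ± 0.31 and Per3 by 2.48 ± 0.29 (adjusted p = 0.345 with an estimated correlation). Of the lymphocyte markers, 6 of the 14 measured members fell (6 adjusted over the list alone) (adjusted p = 0.564 with an estimated correlation). These markers were high in replicates 2 and 3 of the FVB controls, and without these the list's adjusted p was 0.442. The liver list was high in replicate 1 at 12 h, at 3.05.

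At 24 h, cell division genes rose together. Of the mitosis genes, 24 of the 25 measured members rose (24 adjusted over the list alone), with a mean log2 change of 1.35. Among them were the kinesin Kif2c at 1.82 ± 0.31, the anaphase activator Cdc20 at 1.58 ± 0.22 and the checkpoint kinase Bub1b at 1.57 ± 0.26 (adjusted p = 1.21e-29 by camera, adjusted p = 0.0429 with an estimated correlation). Of stress keratins and small proline-rich proteins, 20 of the 23 measured members rose (21 adjusted over the list alone), with Krt16 at 4.64 ± 0.74 (adjusted p = 1.09e-26 by camera, adjusted p = 0.0241 with an estimated correlation). The largest rises of single genes were Stfa3 (5.56 ± 0.71), S100a8 (5.24 ± 0.88), Csta3 (5.23 ± 0.73), Chil1 (5.16 ± 0.72) and S100a9 (5.12 ± 0.74). The largest falls were the stearoyl-CoA desaturase Scd3 by 4.12 ± 0.58, Cyp2g1 by 3.81 ± 0.51, Carns1 by 3.45 ± 0.43, Serpina3b by 3.27 ± 0.53 and Car6 by 3.17 ± 0.66. Of the cytokines and chemokines, 10 of 22 rose (11 adjusted over the list alone) (adjusted p = 0.0727 with an estimated correlation). Sebaceous gland lipid genes were lower in 4 of 16 cases, Scd3 and Mc5r among them (adjusted p = 0.806 with an estimated correlation), and the list's preset adjusted p was 0.0932 without replicate 3 at 24 h. In all, 1032 genes were called at 24 h, 536 higher and 496 lower (51.9% higher, and 72.0% with each array centred on its median). Without the 2 controls with liver transcripts 615 were called. The liver score was 2.04 in replicate 1 at 24 h.

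At 48 h, 1119 genes were called in FVB, 583 higher and 536 lower (52.1% higher, and 69.1% with each array centred on its median). Stfa3 rose by 5.66 ± 0.71, Chil1 by 4.54 ± 0.72, the interleukin 36 gene Il1f6 by 4.44 ± 0.47, Sprr2a1 by 3.94 ± 0.41 and the gasdermin Gsdmc by 3.92 ± 0.42. Falls were largest for Serpina3b (3.92 ± 0.53), Scd3 (3.88 ± 0.58), Cyp2g1 (3.29 ± 0.51), Ifitm6 (2.94 ± 0.69) and Cyp3a57 (2.85 ± 0.42). Of stress keratins and small proline-rich proteins, 15 of the 23 measured members rose (18 adjusted over the list alone) (adjusted p = 1.49e-14 by camera, adjusted p = 0.168 with an estimated correlation). Of the terminal differentiation genes, 9 of the 22 measured members rose (10 adjusted over the list alone), with Lce3c at 2.74 ± 0.50 and the skin protease Asprv1 at 2.53 ± 0.54 (adjusted p = 0.000312 by camera, adjusted p = 0.768 with an estimated correlation). That list's adjusted p was 0.0561 without replicate 2 at 48 h. Of the macrophage markers, 6 of the 15 measured members rose (7 adjusted over the list alone), with Ms4a7 (1.94) and Mrc1 (1.93) (adjusted p = 5.06e-05 by camera, adjusted p = 0.626 with an estimated correlation), but they were highest in replicate 1 at 48 h. Without it the list's adjusted p was 0.305, and those of Ms4a7 and Mrc1 were 0.19 and 0.471. Mrc1 also lost its call without replicate 1, 2 or 3 of the controls (adjusted p = 0.0824, 0.0965 and 0.123), and Ms4a7 without control 3 (adjusted p = 0.0525). Among all genes, 706 were called without replicate 2 of the controls and 225 without its replicates 2 and 3. Ifitm6 and Asprv1 then stood at -2.89 and 2.50 (adjusted p = 0.116 and 0.0856). With all 3 controls, 9 of 25 liver transcripts fell at 48 h.

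At 72 h fewer genes were called in FVB than at earlier times. In all, 353 passed, 177 higher and 176 lower, with Stfa3 at 4.95 ± 0.71, Il1f6 at 4.50 ± 0.47, Stfa1 at 3.25 ± 0.55, the ribonuclease Ang2 at 3.01 ± 0.44 and the chemokine Ccl8 at 2.68 ± 0.65. The falls were led by the nail and hair keratin Krt84 (3.50 ± 0.85), the liver hormone hepcidin Hamp (3.21 ± 0.80), Scd3 (2.61 ± 0.58), Cyp4a31 (2.54 ± 0.58) and the apolipoprotein Apof (2.50 ± 0.65). Of the terminal differentiation genes, 5 of the 22 measured members rose (7 adjusted over the list alone) (adjusted p = 5.97e-07 by camera, adjusted p = 0.553 with an estimated correlation), and of stress keratins and small proline-rich proteins 4 of 23 rose (adjusted p = 0.453 with an estimated correlation). The count was 634 (238 higher, 396 lower) without the 2 narrow arrays, 505 (132 higher, 373 lower) without replicate 1 of the controls, 88 (62 higher, 26 lower) without its replicate 2, 194 without its replicate 3, 212 without replicate 3 at 72 h, and 11 without both controls with liver transcripts. With all 3 controls, 8 of 25 liver transcripts fell at 72 h. Without these 2 controls the liver products Cyp4a31, Hamp and Apof stood at -0.23, -1.48 and -0.91 (adjusted p = 0.963, 0.703 and 0.792). Krt84, Scd3, Ccl8 and Ang2 then stood at -3.04, -2.87, 2.32 and 2.89 (adjusted p = 0.383, 0.183, 0.385 and 0.0624). Among the 10 genes with the largest changes, Stfa3, Il1f6, Stfa1 and Ang2 were called in every leave-one-out. The other 6 each lost their calls without control 2 or 3 or without replicate 1 or 3 at 72 h, with adjusted p between 0.0514 and 0.166. Replicate 3 at 72 h stood apart, with scores of 3.44 for skeletal muscle, 1.97 for adipocytes and 1.20 for macrophages.

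At 168 h the count was at its lowest in FVB, with 72 genes, 48 higher and 24 lower (66.7% higher, and 53.3% after cyclic loess). Il1f6 was still raised by 3.38 ± 0.47 and Stfa3 by 3.36 ± 0.71, followed by Ang2 at 2.62 ± 0.44, Stfa1 at 2.33 ± 0.55 and the retinol transporter Stra6 at 2.22 ± 0.43. The falls were those of Krt84 (3.81 ± 0.85), the hair gene Krtap13 (2.28 ± 0.28), lubricin Prg4 (2.27 ± 0.51), calponin Cnn1 (1.82 ± 0.39) and Tmem45b (1.76 ± 0.38). Of these 10 genes, Il1f6, Krtap13 and Ang2 were called in every leave-one-out, and Ang2 stood at 2.50 (adjusted p = 0.351) without the 2 controls with liver transcripts. The other 7 each lost their calls in at least 1 leave-one-out among the 6 arrays, with adjusted p between 0.0503 and 0.321. Without the 2 narrow arrays 285 genes were called. Counts were 145 (45 higher, 100 lower), 15 and 25 without replicate 1, 2 or 3 of the controls, 8 and 27 without replicate 1 or 2 at 168 h, and 2 without both controls with liver transcripts.

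The 1008 h time is not among those of the treatment protocol, and the labels do not say whether it followed a single dose. FVB skin then differed from untreated skin in 1532 genes, 794 higher and 738 lower (51.8% higher, and 67.3% with each array centred on its median). Hair shaft and inner root sheath genes, which are made in growing hair follicles, rose most: 28 of the 31 measured members rose (28 adjusted over the list alone), with a mean log2 change of 4.08. The keratins Krt27, Krt33a and Krt71 rose by 7.66 ± 1.12, 7.37 ± 1.23 and 7.35 ± 1.07, and the keratin-associated Krtap8-1 and Krtap19-1 by 7.28 ± 1.34 and 6.89 ± 1.19. The list had adjusted p = 4.43e-29 by camera with the preset correlation, and adjusted p = 0.0727 with an estimated correlation. Of 7 hair matrix regulators, members of the same list picked out once the values were known, 5 rose, Hoxc13 by 2.19 ± 0.32 and Dlx3 by 1.66 ± 0.27 among them. Gata3 fell by 1.23 ± 0.39 and Lef1 stood at -0.74 (adjusted p = 0.307). The hair shaft score was also high, at 2.50, in replicate 1 of untreated F1 skin, against -0.31 or less in the other 8 untreated arrays. Stress keratins and small proline-rich proteins were raised as well: 21 of the 23 measured members rose (21 adjusted over the list alone), with Defb3 (6.23), Stfa3 (5.98), Sprr2d (5.10) and Defb4 (5.06) (adjusted p = 7.35e-29 by camera, adjusted p = 0.0202 with an estimated correlation). S100a8 and S100a9 stood at 5.99 ± 0.88 and 6.08 ± 0.74, and Hbegf at 2.21 ± 0.46. Without the 2 controls with liver transcripts Hbegf stood at 1.93 (adjusted p = 0.074). The liver scores of the 3 arrays at 1008 h were 1.27, 1.35 and 1.08.

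Interferon response genes and lymphocyte markers were lower at 1008 h in FVB. Of the former, 13 of the 21 measured members fell (14 adjusted over the list alone), with Cxcl9 down by 3.05 ± 0.65, Usp18 by 2.44 ± 0.38 and Ifit1 by 2.28 ± 0.42 (adjusted p = 7.79e-09 by camera, adjusted p = 0.338 with an estimated correlation). Without the 2 controls with liver transcripts Cxcl9 stood at -2.85 (adjusted p = 0.057). Of the lymphocyte markers, 8 of the 14 measured members fell (8 adjusted over the list alone), with Cd7 down by 2.31 ± 0.32 and Thy1 by 2.12 ± 0.37 (adjusted p = 1.81e-06 by camera, adjusted p = 0.338 with an estimated correlation). That list's adjusted p was 0.0674 without the 2 FVB controls in which it was high and Cd8a, at -1.96 with all controls, then stood at 0.12. Cd8a also lost its call without replicate 2 or 3 of the controls or replicate 1, 2 or 3 at 1008 h, with adjusted p = 0.123, 0.232, 0.0642, 0.0647 and 0.053. Of single genes, the largest falls were those of Ifitm6 by 5.32 ± 0.69, the anion exchanger Slc26a7 by 4.83 ± 0.67, Mrgprb3 by 4.05 ± 0.64, Carns1 by 3.89 ± 0.43 and Scd3 by 3.87 ± 0.58. The 10 largest changes were called in every leave-one-out. Mitosis genes rose in 7 of 25 cases, with Cenpa at 1.22 ± 0.24 (adjusted p = 0.345 with an estimated correlation). Of the pigment genes, Tyr rose by 1.33 ± 0.31 (adjusted p = 0.564 with an estimated correlation for its list).

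**Figure D3:**
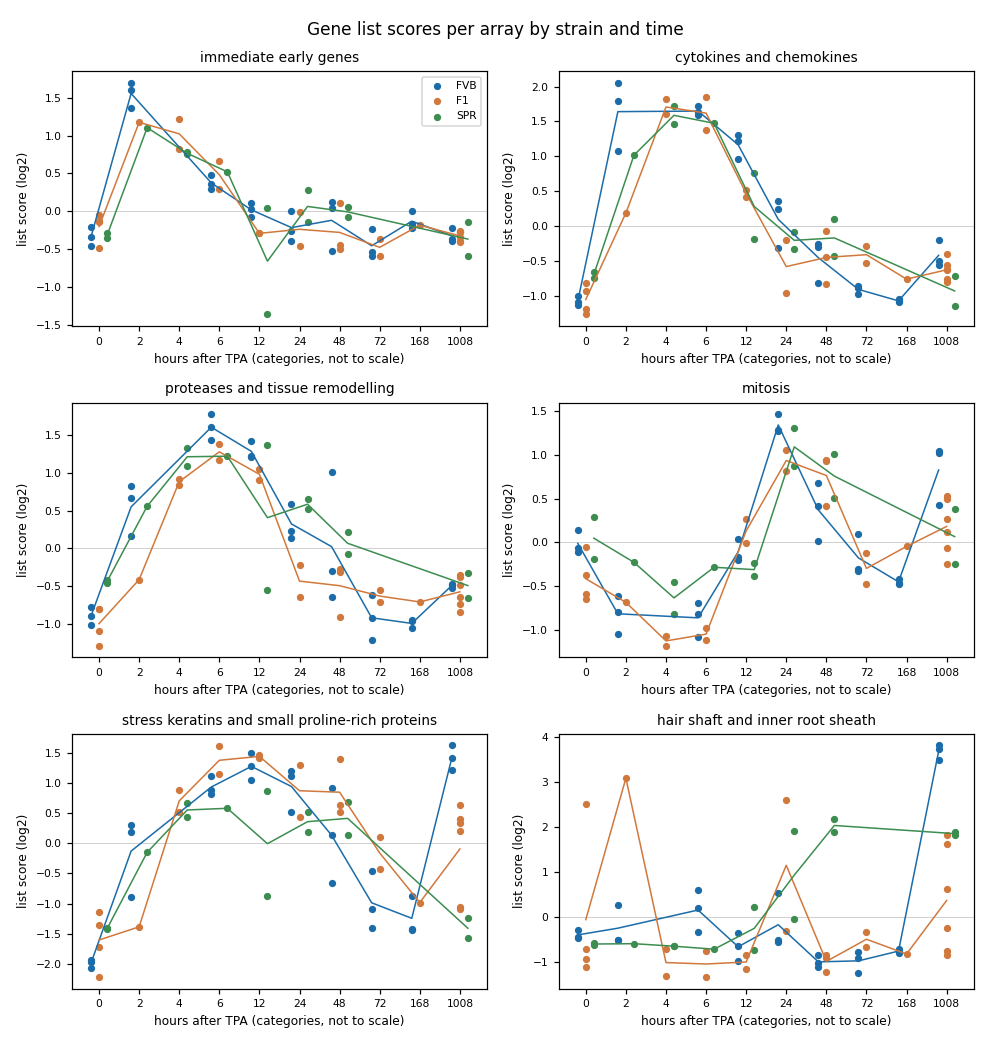
Score of 6 gene lists (vertical axes, mean over the list of log2 values centred on each gene's mean over the assigned arrays) by time in hours, drawn as categories (horizontal axes). Points are arrays and lines join the means of each strain. Hair shaft scores reach 3.48 to 3.81 in FVB at 1008 h and 2.50 in 1 untreated F1 array.

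In F1 skin at 4 h, cytokines and chemokines had the largest mean change of the fixed lists, 2.75. In all, 1973 genes were called, 1027 higher and 946 lower, with Lcn2 at 6.01 ± 0.71, Tnfaip6 at 5.39 ± 0.64 and Cxcl2 at 5.23 ± 0.61 (n = 2 and 4) and with Slc16a14, the glucose transporter Slc2a12 and the stress gene Sesn1 down by 3.62 ± 0.39, 3.15 ± 0.49 and 3.10 ± 0.38. Of the cytokines and chemokines, 18 of the 22 measured members rose (19 adjusted over the list alone) (adjusted p = 1.80e-25 by camera, adjusted p = 0.00117 with an estimated correlation). Of the EGF receptor genes, 9 of the 15 measured members rose (9 adjusted over the list alone), led by Hbegf at 4.09 ± 0.49 (adjusted p = 1.43e-09 by camera, adjusted p = 0.0243 with an estimated correlation). At 6 h 1960 genes were called, 1023 higher and 937 lower. The acute phase genes Saa3 and Saa2 rose by 5.54 ± 0.76 and 5.46 ± 0.97, after Lcn2 at 6.25 ± 0.71. Car6, Mt4 and the alcohol dehydrogenase Adh7 fell by 4.26 ± 0.70, 3.79 ± 0.41 and 3.50 ± 0.41. Proteases rose in 13 of 17 cases, Mmp13 by 4.15 ± 0.66 (adjusted p = 0.0223 with an estimated correlation), and stress keratins and small proline-rich proteins in 19 of 23 (adjusted p = 0.0428 with an estimated correlation). The counts were 1099 at 4 h and 825 at 6 h without replicate 2 of the treated group. Within batches 2 and 3 (1 array against 2 in each) they were 555 and 2697 at 4 h and 373 and 2864 at 6 h. Genes lower outnumbered genes higher within batch 3 (1440 and 1257 at 4 h, 1509 and 1355 at 6 h) and without replicate 1 of the treated group (1142 and 1027, 1224 and 1057). Saa2 had adjusted p = 0.0931 at 6 h within batch 2.

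At 12 h in F1, Lcn2, Defb3 and S100a8 were the most raised, by 5.94 ± 0.71, 5.87 ± 0.80 and 5.69 ± 0.93, and Mt4, the flavin monooxygenase Fmo2 and Carns1 fell by 4.03 ± 0.41, 3.42 ± 0.55 and 3.31 ± 0.46. In all, 930 genes were called at that time, 466 higher and 464 lower (50.1% higher, and 62.9% with each array centred on its median). Of the clock genes, 8 of the 15 measured members fell (8 adjusted over the list alone) (adjusted p = 0.0243 with an estimated correlation). Stress keratins and small proline-rich proteins rose in 19 of 23 cases (adjusted p = 0.0106 with an estimated correlation) and proteases in 13 of 17 (adjusted p = 0.0106 with an estimated correlation). At 24 h mitosis genes rose: 23 of the 25 measured members rose (23 adjusted over the list alone), with Cdc20 at 1.60 ± 0.23 and Plk1 at 1.58 ± 0.25 (adjusted p = 2.89e-48 by camera, adjusted p = 0.00619 with an estimated correlation). At 48 h, 21 of 25 of them were raised, Ccna2 by 1.53 ± 0.26 (adjusted p = 2.25e-54 by camera, adjusted p = 0.00375 with an estimated correlation), and S100a8, S100a9 and Defb3 stood at 5.54 ± 0.82, 4.87 ± 0.69 and 4.72 ± 0.71. In FVB at 48 h the mitosis list had a mean log2 change of 0.38 (adjusted p = 0.831 with an estimated correlation), and the difference of the list's change between the strains at that time, 0.83, had adjusted p = 4.21e-18 by camera and adjusted p = 0.513 with an estimated correlation. At 24 h 356 genes were called (215 higher, 141 lower, that is 60.4% higher, and 70.8% with each array centred on its median) and at 48 h 262 (195 higher, 67 lower). The 12 h count was 542 (193 higher, 349 lower) without its replicate 1 and 388 (254 higher, 134 lower) without its replicate 2. Genes lower at 12 h were also the more numerous without replicate 1, 3 or 4 of the controls (495 and 461, 486 and 457, 387 and 367). The liver scores of the 24 h arrays were 2.65 and 0.86, against -0.72 to -0.14 in F1 controls. The 24 h count was 213 without replicate 2 of the controls, and 192 and 70 without its own replicate 1 or 2. The 48 h count was 120 without its replicate 3. Within batches 2 and 3 the counts were 160 (58 higher, 102 lower) and 1129 (719 higher, 410 lower) at 12 h, 43 and 759 at 24 h, and 48 and 211 at 48 h, and within batch 2 Fmo2 and S100a8 had adjusted p = 0.0741 and 0.0801 at 12 h.

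At 72 h, 374 genes were called in F1, 38 higher and 336 lower (10.2% higher, and 64.1% after cyclic loess). Without replicate 2, the array with the narrow range, limma called 0 genes (242 at an unadjusted p under 0.05), and without replicate 1 it called 4220. Without replicate 2 or 4 of the controls it called 46 and 72. Both arrays are of batch 2, and with the controls of that batch alone 0 genes were called (limma, 2136 at an unadjusted p under 0.05), so genes of this time are not described. 

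At 1008 h, 151 genes were called in F1, 97 higher and 54 lower (n = 6 and 4). Chil1 rose by 3.20 ± 0.57, the kallikrein Klk13 by 2.85 ± 0.48 and Stfa3 by 2.82 ± 0.56, and Ifitm6, Mrgprb3 and Slc26a7 fell by 3.39 ± 0.55, 2.37 ± 0.51 and 2.13 ± 0.53. Of stress keratins and small proline-rich proteins, 10 of the 23 measured members rose (14 adjusted over the list alone), with Krt16 at 2.61 ± 0.59 (adjusted p = 2.91e-26 by camera, adjusted p = 0.0188 with an estimated correlation). The scores of replicates 1, 2, 4 and 5 were 0.64, 0.41, 0.33 and 0.20. Replicates 3 and 6, of batch 2, had -1.05 and -1.10, close to the controls (-2.22 to -1.13, and -1.35 and -1.13 in batch 2). The hair shaft list had a mean log2 change of 0.41 (adjusted p = 0.21 by camera, adjusted p = 0.962 with an estimated correlation). Control 1 had a score of 2.50, against -1.13 to -0.71 in the other controls, and the 1008 h arrays ranged from -0.85 to 1.81. Without control 1 the mean change was 1.34 (preset adjusted p = 3.00e-13). It was 0.53, 0.63 and 0.65 without replicate 4, 5 or 6 at 1008 h (preset adjusted p = 0.0337, 0.00646 and 0.0195), and -0.96 within batch 2 and 2.24 within batch 3. The count was 775 within batch 3 (n = 2 and 2) and 0 within batch 2 (limma, n = 4 and 2, 360 at an unadjusted p under 0.05), where every gene named here had adjusted p = 1. The fit of batch 2 held both narrow arrays and that of batch 3 neither, so these counts rest on different spreads. In the full fit the count was 63 and 83 without replicate 2 or 4 of the controls, and 70, 84 and 255 without replicate 1, 2 or 6 at 1008 h. Krt16 lost its call without control 2 or 4 or replicate 1 at 1008 h (adjusted p = 0.132, 0.0714 and 0.0734), Mrgprb3 without control 2 or replicate 1 (adjusted p = 0.0693 and 0.0562), and Slc26a7 without control 2 or 4 or replicate 1 or 2 (adjusted p = 0.223, 0.126, 0.178 and 0.128).

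In SPR skin at 4 h, cytokines and chemokines had the largest mean change of the fixed lists, 2.28. In all, 991 genes were called, 483 higher and 508 lower (n = 2 and 2, 48.7% higher, and 60.1% after cyclic loess). Lcn2 rose by 5.26 ± 0.82, Cxcl2 by 4.43 ± 0.70 and Stfa3 by 4.25 ± 0.86, and Fads2b, the clock output gene Hlf and Slc16a14 fell by 3.04 ± 0.39, 2.75 ± 0.38 and 2.73 ± 0.45. Of the cytokines and chemokines, 15 of the 22 measured members rose (17 adjusted over the list alone) (adjusted p = 9.04e-28 by camera, adjusted p = 0.0008 with an estimated correlation). Of the proteases 8 of 17 rose (adjusted p = 0.052 with an estimated correlation), and of stress keratins and small proline-rich proteins 12 of 23 (adjusted p = 0.128 with an estimated correlation). Of the interferon response genes, 8 of the 21 measured members rose (15 adjusted over the list alone), with Cxcl10 (2.72) and Ifit1 (2.51) (adjusted p = 5.73e-15 by camera, adjusted p = 0.0821 with an estimated correlation). The count fell to between 537 and 655 without any of the 4 arrays (601 and 550 without replicate 1 or 2 of the controls, 655 and 537 without replicate 1 or 2 at 4 h). Genes higher numbered 243 and genes lower 358 without replicate 1 of the controls, and 329 and 221 without its replicate 2. They numbered 276 and 379 without replicate 1 at 4 h, and 297 and 240 without its replicate 2. The count fell to 10 when SPR was fitted alone, where Lcn2 and Stfa3 had adjusted p = 0.123 and 0.102, and Hlf, Slc16a14, Cxcl10 and Ifit1 had adjusted p between 0.0544 and 0.0979. All 4 arrays are of batch 2, and with that batch fitted alone the count was 852.

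At 24 h, 49 genes were called in SPR (36 higher, 13 lower), led by Saa3 at 5.38 ± 0.90, S100a8 at 5.28 ± 1.1 and Saa2 at 5.26 ± 1.15, with Hsd3b6, the xenobiotic oxidase Cyp1a1 and Sema3d down by 2.50 ± 0.58, 2.46 ± 0.46 and 2.27 ± 0.46. The mitosis list had a mean log2 change of 0.96 (adjusted p = 2.57e-33 by camera, adjusted p = 0.0382 with an estimated correlation) with 2 of 25 members past the gene test. At 48 h, 39 genes were called (31 higher, 8 lower), with 7 of 23 stress keratins and small proline-rich proteins raised (adjusted p = 0.0271 with an estimated correlation) and with the hair follicle genes Tchh and Krt72 at 5.21 ± 1.20 and 4.79 ± 1.12, and Saa3 at 4.37 ± 0.88. Cyp1a1, Sema3d and Paqr7 fell by 2.82 ± 0.45, 2.02 ± 0.45 and 1.71 ± 0.38. At 24 h limma called 0 genes without replicate 1 or 2 at 0 h or at 24 h (592, 927, 986 and 894 at an unadjusted p under 0.05), and the genes named for that time then had adjusted p between 0.0747 and 0.637. At 48 h the count was 1 and 0 without replicate 1 or 2 of the controls and 6 and 0 without replicate 1 or 2 at 48 h (limma, 819 and 569 at an unadjusted p under 0.05 for the counts of 0). Each gene named lost its call in at least 1 of these, with adjusted p between 0.109 and 1. Within batch 2 the counts were 21 and 104. With the 2 narrow arrays left out, 141 and 99 genes were called at these times. With SPR fitted alone 0 were called at 24 h (limma, 433 at an unadjusted p under 0.05).

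At 12 h, 3468 genes were called in SPR, 583 higher and 2885 lower (16.8% higher, 4.50% with median centring and 56.4% after cyclic loess), and 196 (117 higher, 79 lower) without the 2 narrow arrays. The counts were 144 without replicate 1 at 12 h, 11167 without replicate 2, and 1580 and 695 without replicate 1 or 2 of the controls. Genes of this time point are therefore not described. Within batch 2, 2857 were called, and with SPR fitted alone 0 (limma, 2008 at an unadjusted p under 0.05). At 1008 h no gene was called in SPR by limma (358 at an unadjusted p under 0.05), and 2 were without replicate 1 of that group. Within batch 2 the count was also 0 (limma, 175 at an unadjusted p under 0.05). With SPR fitted alone 9 genes were called at 1008 h, 9 higher and 0 lower. The stress keratin list had a mean log2 change of 0.04, and that of hair shaft genes was 2.51 (adjusted p = 5.52e-48 by camera, adjusted p = 0.0271 with an estimated correlation, with 0 of 31 members past the gene test and 21 adjusted over the list alone).

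The responses of the strains were then compared directly, as the change from 0 h in one strain less that in the other. Between F1 and FVB, 354 genes differed over 6, 12, 24, 48, 72 and 1008 h. The count was 1018 without the 2 narrow arrays, 1496 after cyclic loess and 259 with F1 arrays of batch 2 alone. The 10 largest F statistics included the interleukin 12 receptor gene Il12rb2, which changed by -2.55 in FVB and -0.24 in F1 at 1008 h (difference 2.31 ± 0.32, adjusted p = 1.64e-06 over all times). Adh6a changed by -2.48 and 0.09, and the class I gene H2-Q6 by -2.52 and -0.28. The hair matrix regulator Msx2 changed by 1.46 in FVB and -0.60 in F1, Tent5b by 1.59 and -0.44, Sult5a1 by -2.48 and -0.53, Krtap13 by -2.08 and -0.05, and the peptide transporter Slc15a2 by -1.13 and 0.40. Hair shaft genes as a list changed less in F1 at 1008 h, with a difference of mean log2 changes of -3.67 (adjusted p = 5.32e-41 by camera, adjusted p = 0.159 with an estimated correlation). Without control 1 of F1, high in these genes, it was -2.74 (preset adjusted p = 1.07e-35, and adjusted p = 0.232 with an estimated correlation). Stress keratins and small proline-rich proteins, close to control scores in F1 replicates 3 and 6, differed by -1.90 (adjusted p = 6.76e-17, and adjusted p = 0.357 with an estimated correlation), and interferon response genes by 1.22 (adjusted p = 3.08e-11, and adjusted p = 0.513 with an estimated correlation). FVB was measured in batch 1 alone and the other strains in batches 2 and 3, so strain and batch cannot be told apart in these differences.

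Between SPR and FVB, 3860 genes differed over 12, 24, 48 and 1008 h. The count was 1104 without the 2 narrow arrays, 1960 after cyclic loess and 546 with SPR arrays of batch 2 alone. The interleukin 36 gene Il1f6 changed by 5.34 in FVB and -0.41 in SPR at 1008 h (difference -5.75 ± 0.75, adjusted p = 6.35e-05 over all times), and at 48 h by 4.44 and 3.31. Gsdmc changed by 3.92 in FVB and 0.46 in SPR at 48 h and by 3.55 and -0.43 at 1008 h. Tmprss11a changed by 3.27 and -0.35 at 1008 h, Pla2g4d by 2.25 and -0.29 (SPR last in each pair), Sgpp2 by 2.14 and -0.10, Sema3d by -3.34 and 0.06, and Paqr7 by -3.29 and -0.22. Tmem45b changed by -2.39 in FVB and 1.19 in SPR at 48 h. Its untreated level differed by -2.56 in SPR less F1, so a fall could show less in SPR. Whether the probes of Tmem45b and Gsdmc read SPR transcripts poorly was not tested. For stress keratins and small proline-rich proteins at 1008 h the difference of mean log2 changes was -3.36 (adjusted p = 1.32e-27 by camera, adjusted p = 0.0746 with an estimated correlation). SPR and F1 both lay in batches 2 and 3, but SPR arrays at 0, 4, 12 and 48 h were all of batch 2. F1 had controls in both batches, and the batch term only shifts levels, so a batch difference in scale is not separated from strain. Between SPR and F1, 2 genes differed over 4, 12, 24, 48 and 1008 h (moderated F test, both adjusted p = 0.0479). Fosb was at 1.33 in SPR and -1.47 in F1 at 24 h, and the alarmin Il33 at -0.92 and 0.65 at 4 h. In F1 Fosb was about as low at 12, 48 and 1008 h (-1.80, -1.68 and -1.78), all against the same controls. Limma called 0 without the 2 narrow arrays, with median centring, with all probe sets, with no batch term and over genes whose untreated level in SPR lay within 1 log2 unit (939, 3592, 3758, 3040 and 3064 at an unadjusted p under 0.05). Of 420 tests of list differences over the 3 pairs of strains, 168 were called by camera and 1 with an estimated correlation. That was the hair shaft list at 48 h, which changed by 2.64 in SPR and -0.95 in F1 (difference 3.59, adjusted p = 0.0189 with an estimated correlation). Without control 1 of F1 the difference was 2.65, and its p was then 0.0608. Without SPR control 2 or SPR replicate 1 at 48 h it was 3.57 and 3.44 (adjusted p = 0.0565 and 0.052 with an estimated correlation).

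The changes were also correlated between strains. Across 18820 genes, which are not independent replicates, Pearson's r between the log2 changes of FVB and F1 was 0.82, 0.78, 0.62, 0.51, 0.21 and 0.61 at 6, 12, 24, 48, 72 and 1008 h. Spearman's rho was 0.72, 0.69, 0.57, 0.43, 0.25 and 0.50. Between FVB and SPR r was 0.19, 0.53, 0.28 and 0.36 at 12, 24, 48 and 1008 h, and rho 0.12, 0.42, 0.30 and 0.04. Between F1 and SPR r was 0.83, 0.24, 0.59, 0.37 and 0.14 at 4, 12, 24, 48 and 1008 h, and rho 0.72, 0.17, 0.47, 0.39 and -0.01. F1 at 72 h and SPR at 12 h each hold a narrow array. The strains share no control arrays. Of the genes called in FVB, 98.4%, 97.8%, 96.3%, 83.6%, 62.9% and 88.7% had a change of the same sign in F1 at these 6 times. In SPR it was 62.5%, 92.2%, 79.8% and 61.0% at the 4 times shared with FVB. Of the genes called in F1, 97.9%, 76.1%, 95.2%, 93.9% and 62.9% had the same sign in SPR.

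Untreated SPR and F1 skin differed in 45 genes, all lower in SPR (n = 2 and 4). The cytochrome Cyp2g1 differed by -5.13 on the log2 scale after the batch term (group means 6.54 in SPR and 11.40 in F1), the ion channel relative Ano9 by -3.66, the acute phase gene Orm1 by -3.14, Tmem45b by -2.56 and Skint10, of a family expressed in keratinocytes, by -2.56. Probes designed on another mouse strain can read SPR transcripts as lower, and levels of FVB could not be compared with the others because batch and strain coincide. Within batch 2 (n = 2 and 2) 11 genes were called, after cyclic loess 68 (8 higher, 60 lower), and without the 2 narrow arrays 71 (11 higher, 60 lower).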

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

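The tests of the hair, liver and stress keratin patterns were chosen after these patterns were seen, except for the test of scale in the liver pattern, and the SPR test at 48 and 1008 h replaced an earlier one within batch 2 that rested on 1 array at 1008 h and had pointed the same way.

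In replicate 1 of untreated F1 skin the hair shaft and inner root sheath score was 2.50, far from the other 3 arrays of that group (-1.13 to -0.71). In replicate 2 of the same group the skeletal muscle score was -1.20, against 0.91 to 1.34 in the others. Chance picks out about 1 in 20 groups, and 56 combinations of group and list were examined. In moderated F tests, the change from 0 h differed between F1 and FVB in 354 genes, between SPR and FVB in 3860 and between SPR and F1 in 2. Without the 2 narrow arrays these counts were 1018, 1104 and 0 (limma, 939 at an unadjusted p under 0.05). The hair shaft list changed more in SPR than in F1 at 48 h, by 3.59 (adjusted p = 0.0189 with an estimated correlation), where SPR had 2 arrays with scores of 1.88 and 2.17. Without the F1 control at 2.50 the difference was 2.65 (adjusted p = 0.0608 with an estimated correlation). The 3 arrays without a strain in the labels, 1 at 2 h, 1 at 6 h and 1 without a time, had immediate early gene scores of 1.06, 0.72 and 1.18, against -0.49 to -0.05 in the untreated arrays. Their cytokine and chemokine scores were 0.65, 2.06 and 1.30, against -1.26 to -0.65.

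Hair shaft and inner root sheath genes stood 4.08 higher at 1008 h in FVB. The tables argue against scaling of the arrays, with a mean change of 4.18 after cyclic loess. Hair fibres carried into the sample bring shaft transcripts without those of matrix regulators, and 5 of 7 regulators rose. All 7 are members of the same hair list, most of which rose, and were picked once the values were known. Their count is thus no separate test and does not decide on hair fibres. A hair growth stage that skin can reach without TPA stays open, because 1 of 9 untreated arrays, the F1 array at 2.50, reached the range of the 12 highest treated arrays of all strains (1.60 to 3.81). It did not reach the FVB arrays at 1008 h (3.48 to 3.81). The untreated FVB arrays scored -0.47, -0.44 and -0.31. An effect of TPA and the age of the mice at 1008 h also stay open as untested, since no untreated skin of that age was among the samples, and whether 1008 h followed a single dose is not in the labels.

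In FVB controls 2 and 3, 25 of 25 liver transcripts lay at least 1 log2 unit above control 1, with Alb at 8.38 in control 1 and at 10.29 and 10.39 in the others. Over 5234 genes of the same mean level the 2 arrays differed from control 1 by medians of -0.07 and -0.10. The rise was thus not shared by genes of that level in general. RMA sets arrays to a common distribution, which keeps such medians small, so the test cannot decide on a difference in scale. Liver RNA or tissue in the sample is a candidate source, from a list of which 0 genes are held by the lists fixed beforehand. It leaves open why 8 of 14 pancreas transcripts were also higher in both arrays, and where the high liver scores of treated arrays came from, such as 3.05 in replicate 1 at 12 h. The labels give no tissue other than skin, and no biological explanation was tested.

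Stress keratins and small proline-rich proteins changed by a mean of 3.40 at 1008 h in FVB, 1.5 in F1, where 2 of 6 arrays scored close to the controls, and 0.04 in SPR. For SPR, values of batch 2 compressed when batches were aligned before deposit are argued against as the whole cause, because every array at 48 h, all of batch 2, scored at least 1.38 above every array at 1008 h. Probes of the list that read SPR transcripts poorly are also argued against, since 12 members rose in SPR at 4 h. For F1, compression of batch 2 cannot be told apart from a difference between strains, which stays open because FVB lies in a batch of its own. The F1 change was 2.49 within batch 3 and 0.84 within batch 2, whose arrays at 1008 h had scores of -1.05, 0.33, 0.20 and -1.10 against -1.13 and -1.35 in its controls, and F1 changes projected on FVB changes had ratios of batch 2 to batch 3 of 0.67, 0.77, 1.01 and 0.80 at 6, 12, 24 and 48 h.

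Other splits of the arrays were refitted with limma. For each FVB time there are 10 splits, too few for a share under 0.05. The real count and the highest of the others were 1258 and 3 at 2 h, 2319 and 264 at 6 h, 1958 and 480 at 12 h, 1032 and 195 at 24 h. They were 1119 and 32 at 48 h, 353 and 1 at 72 h, 72 and 0 at 168 h (328 at an unadjusted p under 0.05 in 1 such split) and 1532 and 0 at 1008 h (628 at an unadjusted p under 0.05 in 1 such split). The highest other split at 12 h set control 1 and replicates 2 and 3 against controls 2 and 3 and replicate 1 at 12 h, which are the arrays with liver scores of 2.07, 2.60 and 3.05. The split at 24 h was of the same form. In F1 at 48 h, 1 of 35 splits gave 262 genes or more, the real one, and the highest other gave 99. The F1 splits, here and at 1008 h, mixed arrays of batch 2 and batch 3, so they do not exclude chance. In F1 at 1008 h, 3 of 100 splits drawn from 210 gave 151 genes or more, a share under 0.05. The highest other, 267, set replicates 3 and 6 at 1008 h with the 4 controls and so points to a structure among the 1008 h arrays. Within batch 2 the real count was 0 (360 at an unadjusted p under 0.05) and within batch 3 it was 775. Only the fit of batch 2 held the narrow arrays, so these counts rest on different estimates of spread. Over the FVB time course, 1 of 100 drawn assignments gave 9588 genes or more, the real one, and the highest other gave 1733. Chance can thus be excluded if the arrays vary independently. The labels do not tie each array to a mouse of its own, so chance differences between mice are not excluded.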

How the results depend on the processing

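Leaving out the 2 narrow arrays, the 2 FVB controls with liver transcripts or the 3 FVB arrays that stood apart in lists of cell types (replicate 3 at 6 h, replicate 1 at 48 h, replicate 3 at 72 h) was chosen after the results were seen, and all other alternatives were planned. Of 298 counts under other settings 217 lay within 1.5 times the reported ones, and of 115 counts with 1 array left out 71 did. Of 8879 values of named genes under other settings, 7865 kept direction and call, 987 lost the call and 27 changed sign. With 1 array left out it was 4278, 1119 and 18 of 5415. Of 2674 list tests under other settings 2262 kept direction and call, 407 lost the call, 220 of them with an estimated correlation, 2 gained it and 3 changed sign. With 1 array left out it was 1363, 139, 4 and 2 of 1508. The deposited values hold no detection calls, so signal over background is not known here. With dim probe sets left out, 925 of 936 named gene results had a value and all of these kept their call, as did 228 of 255 lists. The other named results lay on probe sets left out as dim. SPR has no controls in batch 3 and F1 no 72 h array there, so these had no value within that batch. Named genes and lists were not run over all probe sets, without the fold threshold or over genes of similar level in SPR.

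The counts beyond 1.5 times the reported ones follow, with the number at an unadjusted p under 0.05 by limma in brackets after a 0, and the cause was not tested. With arrays centred on their medians, FVB gave 211 at 72 h. F1 gave 119 at 72 h. SPR gave 20 at 48 h. The count was 0 (3592 unadjusted) for SPR less F1. After cyclic loess, FVB gave 604 at 72 h and 244 at 168 h. F1 gave 128 at 72 h. SPR gave 342 at 12 h, 109 at 24 h, 96 at 48 h and 2973 for the F test over times. The count was 1496 for F1 less FVB, 1960 for SPR less FVB, 6 for SPR less F1 and 68 for untreated SPR against F1. With all probe sets, the count was 0 (3758 unadjusted) for SPR less F1. With no fold threshold, FVB gave 2706 at 2 h, 4653 at 6 h, 4264 at 12 h, 2535 at 24 h, 2498 at 48 h, 622 at 72 h and 3374 at 1008 h. F1 gave 3868 at 4 h, 3569 at 6 h, 1709 at 12 h, 399 at 48 h, 740 at 72 h and 314 at 1008 h. SPR gave 6163 at 12 h. With each strain fitted alone, FVB gave 189 at 168 h. F1 gave 587 at 72 h. SPR gave 10 at 4 h, 0 (2008 unadjusted) at 12 h, 0 (433 unadjusted) at 24 h, 10 at 48 h, 9 at 1008 h and 17 for the F test over times. Without a batch term, the count was 0 (3040 unadjusted) for SPR less F1. Within batch 2, F1 gave 555 at 4 h, 373 at 6 h, 160 at 12 h, 43 at 24 h, 48 at 48 h, 0 (2136 unadjusted) at 72 h, 0 (360 unadjusted) at 1008 h and 908 for the F test over times. SPR gave 21 at 24 h, 104 at 48 h and 2393 for the F test over times. The count was 546 for SPR less FVB, 25 for SPR less F1 and 11 for untreated SPR against F1. Within batch 3, F1 gave 759 at 24 h and 775 at 1008 h. Over genes with an SPR level at 0 h within 1 log2 unit of the other strain, the count was 0 (3064 unadjusted) for SPR less F1. Without the 2 narrow arrays, FVB gave 634 at 72 h and 285 at 168 h. F1 gave 0 (452 unadjusted) at 72 h. SPR gave 196 at 12 h, 141 at 24 h, 99 at 48 h and 2544 for the F test over times. The count was 1018 for F1 less FVB, 1104 for SPR less FVB, 0 (939 unadjusted) for SPR less F1 and 71 for untreated SPR against F1. Without the 2 FVB controls with liver transcripts, FVB gave 758 at 2 h, 615 at 24 h, 225 at 48 h, 11 at 72 h and 2 at 168 h.

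Leaving out each array in turn gave counts in F1 of 1099 to 2169 at 4 h, 825 to 2281 at 6 h, 388 to 956 at 12 h, 70 to 472 at 24 h, 120 to 264 at 48 h, 0 (242 unadjusted) to 4220 at 72 h and 63 to 255 at 1008 h. FVB counts ran over 803 to 1473 at 2 h, 706 to 1371 at 48 h, 88 to 505 at 72 h and 8 to 145 at 168 h. SPR counts ran over 537 to 655 at 4 h, 144 to 11167 at 12 h, 0 (592 unadjusted) at 24 h, 0 (819 unadjusted) to 6 at 48 h and 0 (271 unadjusted) to 2 at 1008 h. For these too the cause was not tested.

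Replicate numbers were checked for pairing within each strain. Same-numbered FVB arrays deviated together with a mean correlation of -0.0051 over 108 pairs, against 0.0023 for other pairs, 22 pairs exceeded 0.1, and 8 of 27 arrays correlated best with their own number. In F1 the mean was -0.0069 over 60 pairs against 0.0026, after the batch term, 15 pairs exceeded 0.1, and 5 of 21 arrays correlated best with their own number. In SPR the mean was -0.0027 over 30 pairs against 0.0027, after the batch term, 8 pairs exceeded 0.1, and 6 of 12 arrays correlated best with their own number. The arrays thus share only a number. With the replicate block, F1 gave 224 at 24 h, 5 at 72 h and 247 at 1008 h. SPR gave 80 at 24 h, 86 at 48 h and 2 at 1008 h. The count was 58 for F1 less FVB, 9 for SPR less F1 and 12 for untreated SPR against F1. The other counts stayed within 1.5 times under the block. Of the lists, 9 lost their call under it, and the hair shaft list in F1 at 1008 h, not called at 0.41, stood at 1.01 (adjusted p = 8.08e-07).

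Genes that had fallen in SPR at 12 h were above 0 after cyclic loess, with log2 changes of Pcna 0.17, Postn 0.22, Errfi1 0.19, Spred1 0.023, Xist 0.05, Hspa5 0.19 and Hsp90b1 0.20. Without the 2 narrow arrays, genes of SPR at 12 h stood at Dusp1 0.047, Epcam 0.20, Cd207 0.16, Pcna 0.34, Rrm1 0.086 and Asprv1 0.14. Others were at Krt5 0.005, Krt14 0.18, Col17a1 0.12, Postn 0.28, Cd36 0.14 and Egfr 0.002. The rest were at Errfi1 0.09, Spred1 0.24, Gsta4 0.001, Hspa8 0.15, Hspa5 0.73 and Hsp90b1 0.61. These are also the highest values with 1 array left out, replicate 1 at 12 h. The lowest with 1 array left out were Dusp1 -3.29, Epcam -3.27, Cd207 -3.15, Pcna -2.83, Rrm1 -2.23 and Asprv1 -5.49. Then came Krt5 -5.09, Krt14 -4.17, Col17a1 -3.63, Postn -3.34, Cd36 -3.17 and Egfr -2.80. Last were Errfi1 -2.79, Spred1 -2.48, Gsta4 -2.25, Hspa8 -4.20, Hspa5 -3.70 and Hsp90b1 -3.29. The cause was not tested. Cd8a in FVB stood at 0.076 at 12 h and 0.12 at 1008 h without the 2 controls with liver transcripts, which were high in lymphocyte markers. The hair shaft list in F1 at 24 h, at 1.21, was -1.21 within batch 2 and -0.45 to 2.86 with each array left out. That list in F1 at 1008 h, at 0.41, was -0.96 within batch 2, 2.24 within batch 3 and 0.03 to 1.34 with each array left out. The F1 controls of batch 2 had hair shaft scores of 2.50 and -0.71, and those of batch 3 -1.13 and -0.94. The stress keratin list in SPR at 1008 h, at 0.04, was -0.005 with arrays centred on their medians and -0.12 to 0.17 with each array left out. For these the cause was not tested.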

Other observations

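No test here was chosen after the results were seen and the gene lists were fixed before the data were examined, but which lists and genes to describe was chosen afterwards. Genes of the circadian clock changed within hours of TPA. In FVB at 12 h, 7 of 15 measured members fell and 2 rose (adjusted p = 0.345 with an estimated correlation). The clock output gene Hlf changed by -2.68 at 6 h and -2.49 at 12 h, and Per3 by -2.33 and -2.48. The clock repressor Bhlhe40 rose by 2.70, 2.26 and 1.84 at 2, 6 and 12 h. In F1 at 12 h, 8 of 15 members fell, with a list mean of -1.10 (adjusted p = 0.0243 with an estimated correlation), among them Hlf at -3.12, Tef at -2.76 and Per2 at -2.62. The hour of day of sampling is not in the labels, and the untreated arrays are all of 0 h. In SPR at 4 h Hlf changed by -2.75 and Per3 by -2.12, with adjusted p = 0.0544 and 0.123 where SPR was fitted alone.

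Lgr5, a marker of hair follicle stem cells, fell by 2.59 ± 0.34 in FVB at 6 h and by 2.66 ± 0.36 and 2.83 ± 0.36 in F1 at 4 and 6 h. In SPR at 4 h it fell by 1.81 ± 0.41, with adjusted p = 0.098 without replicate 2 at 0 h and 0.0652 without replicate 2 at 4 h. The cystine transporter gene Slc7a11, a target of the oxidative stress regulator NRF2, rose by 2.90 ± 0.61 in FVB at 6 h, and by 4.66 ± 0.65 and 3.91 ± 0.75 in F1 and SPR at 4 h. Of the NRF2 list, 3 of 12 rose in FVB at 6 h (adjusted p = 0.963 with an estimated correlation). Of heat shock and unfolded protein response genes, 4 of 10 rose at that time (adjusted p = 0.794 with an estimated correlation), with the chaperone gene Dnajb9 at 1.63 ± 0.38. The melanocortin receptor gene Mc5r, active in sebaceous glands, fell in FVB by 1.99, 1.74, 1.63 and 2.25 at 6, 12, 24 and 48 h.

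Groups of 1 array entered no test. In F1 at 2 h the immediate early gene score was 1.18, the cytokine score 0.19 and the hair shaft score 3.08. For F1 at 168 h the immediate early gene score was -0.18 and the cytokine score -0.76. The SPR array at 2 h had scores of 1.11 and 1.02 for these lists, and that at 6 h 0.52 and 1.47, with 1.22 for proteases.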
